A study of Mus musculus with 8 samples.

How the data were processed

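The values are those of the deposited series table, with 22690 probe sets on 8 arrays: 3 of LSK cells, 3 of WT LICs and 2 of Ezh2 KO LICs. Per the labels' protocols, marrow was stained and the cells sorted straight into lysis buffer, with each sample passed through the sorter 2 times, and total RNA was amplified by isothermal single-primer amplification before biotin labelling. The submitters' processing notes name RMA, with no version. The deposited values were linear intensity values between 1.94 and 19343.1, not log2 values. The sorted log2 values of the arrays differed by an SD of at most 0.08, so the arrays had been brought to a common distribution. Background correction and any later step are not given in the sources used here.

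Each deposited intensity was turned into log2 with no pseudocount, since all values were above 0. Log2 values had been assumed when the design was fixed, and the test stayed the same. Control probe sets (64) were left out. Of the rest, 20380 had 1 gene symbol, 691 had several and 1555 were not listed in the annotation; the last 2 kinds entered no test of genes. Of those with 1 symbol, 20364 matched by gene number to the RefSeq table of assembly GRCm38.p6, used for names and for which genes neighbour each other; no build is stated for the arrays and no coordinate is given. Each gene was represented by its probe set with the highest mean over the 8 arrays, which gave 12393 genes, with no filter on dim ones. Where a group mean lay at or under 4.01, the highest mean among 27 unspiked bacterial control probe sets, a fold is given as a lower bound against that level. Probe set brightness was not compared between genes.

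The 3 groups were fitted together in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, with group as the only term, which left 5 residual degrees of freedom. Tests were 2-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over the 12393 genes were called. Exact permutation tests of single values were not used, since 3 arrays against 3, or 2 against 3, cannot go below p = 0.1. Of 35 gene lists fixed before the data were examined, 34 were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 34 lists; the list of sex-linked markers served only to describe samples. fry asks whether the genes of a list move on balance one way and does not compare them with other genes. With an estimated correlation camera also used the 5 residual degrees of freedom, so a lost call does not by itself point to correlated genes. For WT LICs against LSK cells the sterol list had an estimated correlation of -0.0443, below the preset. Its unadjusted camera p still rose from 2.84e-05 to 0.00612. Members were also counted with p adjusted over the list alone. Plots were drawn with matplotlib 3.10.9.

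Genes were named by a rule fixed before the data were examined. Ezh2 and Ezh1 were always named, and Cdkn2a, Cdkn2b, Cdkn1a and Cdkn1c for the knockout comparison. To these were added the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap between the groups and whose higher group mean exceeded 7.20, the median of all genes on the log2 scale. Predicted genes, clones, receptor and antibody segments, small RNAs and histone genes were passed over. For each list described, up to 4 members with the smallest p were named. Genes named outside this rule are said to have been chosen after their values were seen.

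On simulated arrays, 200 genes at a time were given known changes. Each gene had its mean over all arrays plus normal noise with the SD of its fit, drawn separately for each gene. Variation that genes share on an array, and arrays that vary more than others, were left out, so the real arrays may do less well. For WT LICs against LSK cells, 40.3% of genes changed by 1 on the log2 scale, 95.5% of those changed by 2 and 97.0% of those changed by 4 were recovered, with 7 false calls among 162. For Ezh2 KO against WT LICs the shares were 28.4%, 88.1% and 97.0%, with 12 false calls among 154.

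No scan date or other batch was given, so hybridisation batch and group cannot be told apart. LICs came from transplanted animals and no transplantation is given for LSK cells, so the comparisons with LSK cells hold transplantation, retroviral infection and leukaemia together. The sex of the animals and any pooling are not given in the sources used here. Since sex-linked transcripts separated LSK cells from LICs, a difference in sex and the group cannot be told apart in those comparisons. Igk and Jchain were brighter in LSK cells than in LICs, and antibody-secreting cells carried through the LSK sort were not tested for. Alternatives were a filter on dim genes, median centring, quantile normalization, cyclic loess, a trended robust prior, array weights, a fit of the compared groups alone, the repeat number as a block, each array left out, the mean of all probe sets, all probe sets, a size threshold and an estimated correlation. A floor at an intensity of 32 and the removal of sex-linked genes were added after the data were seen.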

Results

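Gene expression was measured on Affymetrix 3′ expression arrays in blood-forming cells of mice. LSK cells, the fraction of bone marrow that lacks lineage markers and carries Sca1 and Kit, came from normal 12-week-old C57BL/6 animals and are enriched for stem and multipotent progenitor cells. Leukaemia-initiating cells (LICs) had the same surface markers plus GFP and came from a retroviral model of chronic myeloid leukaemia, 14 days after transplantation. The LICs were wild type (WT) or lacked Ezh2, the enzyme of Polycomb repressive complex 2 that methylates histone H3 at lysine 27 (Ezh2 KO). There were 3 LSK arrays, 3 WT LIC arrays and 2 Ezh2 KO LIC arrays, and the labels call the repeats biological. The median of an array ranged from 6.42 to 6.57 on the log2 scale. The number of arrays limits the precision: the median standard error of a gene's log2 difference was 0.207 between WT LICs and LSK cells and 0.232 between Ezh2 KO and WT LICs.

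Ezh2 itself was lower in the knockout cells, at 8.94 and 9.55 (log2) on the 2 Ezh2 KO arrays against 11.34 ± 0.09 (SD, n = 3) in WT LICs and 10.93 ± 0.15 (SD, n = 3) in LSK cells. It fell by 2.10 on the log2 scale, a 4.29-fold difference, between WT and Ezh2 KO LICs (SE 0.21, adjusted p = 0.00985, limma). A single probe set reports Ezh2. Whether it lies within the deleted part is not given in the sources used here, so the signal gives the level of the measured part and does not check the deletion. Its relative Ezh1 was at 7.83 in WT and 6.62 in Ezh2 KO LICs, a difference that did not pass the test (adjusted p = 0.212). Among 11 measured Polycomb repressive complex 2 subunits, Ezh2 alone was called between WT and Ezh2 KO LICs, and Ezh2 and Ezh1 adjusted over the list alone. Fitted on the 5 LIC arrays alone, the Ezh2 difference had an adjusted p of 0.055, the highest of the alternatives, which ranged from 0.00231 to 0.055.

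**Figure D1:**
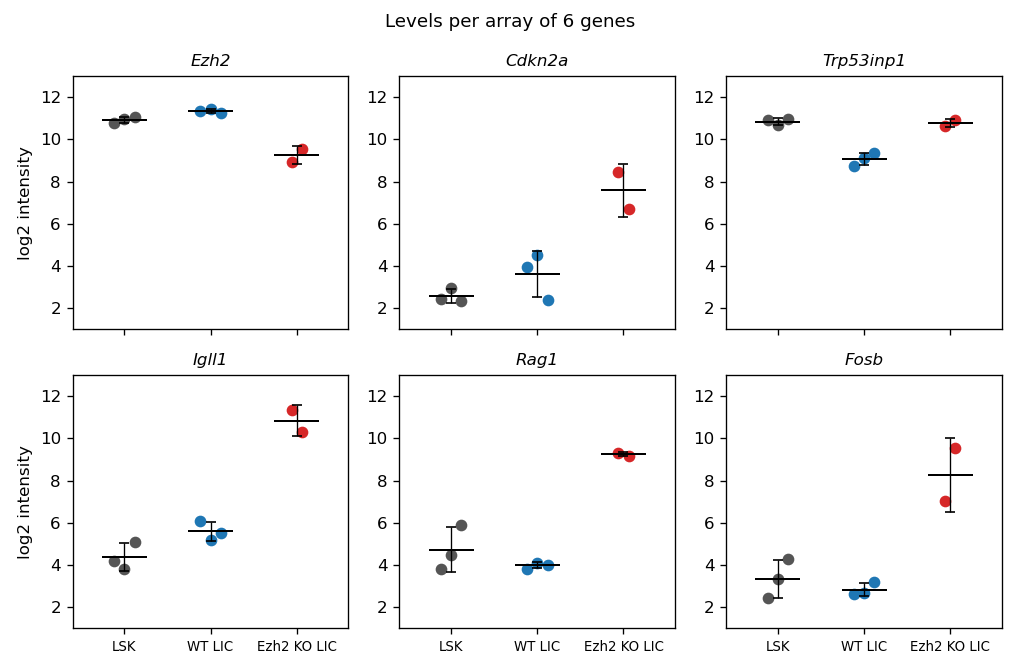
Log2 intensity (y axis) of 6 genes on each of the 8 arrays, by group (x axis). Points are arrays, horizontal lines are group means and bars are 1 SD. Ezh2 lay at 8.94 and 9.55 on the 2 Ezh2 KO arrays and above 10 on the others, while Igll1 and Rag1 lay above 9 on both Ezh2 KO arrays and under 7 on the others.

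The first comparison asked how WT LICs differ from normal LSK cells. WT LICs had more RNA of dividing cells and of sterol synthesis and less of stem-cell, platelet-lineage and lymphoid-progenitor genes. Each of these list calls was lost with an estimated correlation: adjusted p = 0.131 with an estimated correlation for the G2/M, sterol and stem cell lists, 0.19 for the megakaryocyte list and 0.42 for the progenitor list. Socs2, a feedback inhibitor of cytokine signalling that STAT5 induces, rose 3.38 on the log2 scale (SE 0.27, adjusted p = 0.00163), to 11.71 ± 0.33 (SD, n = 3) from 8.33 ± 0.44 (SD, n = 3). Kit, the stem cell factor receptor used in the gate, fell by 1.19 (SE 0.14, adjusted p = 0.00886). In all, 424 of 12393 genes changed, 157 higher and 267 lower in WT LICs.

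Apart from Y-linked genes, the rises picked by the naming rule were those of Enah, an actin regulator, which was at least 54.9-fold higher in WT LICs (adjusted p = 0.000149), and Ccn3, a secreted matricellular protein, which was at least 17.7-fold higher (adjusted p = 0.000149). Pmaip1, which encodes the pro-apoptotic protein Noxa, was at least 26-fold higher (adjusted p = 0.0167). Tph1, which encodes a serotonin-synthesis enzyme, was at least 12.1-fold higher (adjusted p = 0.0222), with an SD of 1.52 over the 3 WT LIC arrays. Pmaip1 lost its call without LSK replicate 2 or WT LIC replicate 2 (adjusted p up to 0.0594 over the alternatives), and Tph1 without any 1 LSK array or without WT LIC replicate 2 (up to 0.166). The 4 probe sets of Enah disagreed, and 1 of them lay under background, at 3.95 or lower, on each LSK and WT LIC array. The falls picked by that rule, which passes over antibody segments, were those of Jchain, the joining chain of secreted antibody, which fell by 5.77 (SE 0.32, adjusted p = 0.000281), and of the transporter Abcg3, at least 25.9-fold lower (adjusted p = 0.000263). Cavin2, a caveolar protein, was at least 28.7-fold lower (adjusted p = 0.00146). Sult1a1, a sulfotransferase, was at least 20-fold lower (adjusted p = 0.00261), and the cation channel Trpc6 at least 21.6-fold lower (adjusted p = 0.00398). The non-coding Gt(ROSA)26Sor transcript was at least 10.1-fold lower (adjusted p = 0.00369). Each "at least" is taken against the highest mean among unspiked bacterial control probe sets, 4.01 on the log2 scale, because the dimmer group lay at or below it.

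Cell-cycle genes rose as a group. Of 44 measured G2/M genes, 9 rose, none fell and 35 did not pass, or 22 adjusted over the list alone, with a median change of 0.58 (camera adjusted p = 3.95e-13; adjusted p = 0.131 with an estimated correlation). Nuf2, a kinetochore component, rose 1.08 (SE 0.13), the mitotic kinase gene Plk1 rose 1.26 (SE 0.20) and Cdc20 rose 1.49 (SE 0.24). Of 37 G1/S genes, 2 rose, Exo1 by 1.12 and Ccne1 by 1.96, and also 2 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.000549; adjusted p = 0.197 with an estimated correlation). MYC target genes of ribosome biogenesis moved the same way, with 1 of 25 called, Odc1, and 8 adjusted over the list alone (median 0.33, adjusted p = 5.01e-07; adjusted p = 0.204 with an estimated correlation). Of 19 sterol and fatty acid synthesis genes, 3 rose, or 5 adjusted over the list alone (median 0.57, adjusted p = 0.000161; adjusted p = 0.131 with an estimated correlation). Lss, the lanosterol synthase gene, rose 1.83 (SE 0.18), Idi1 rose 1.11 (SE 0.21) and Fdps rose 1.05 (SE 0.20). Nuclear oxidative phosphorylation genes shifted by a median of 0.18, with 1 of 55 called, Cyc1, and none adjusted over the list alone (adjusted p = 0.000571; adjusted p = 0.644 with an estimated correlation), and without WT LIC replicate 1 the adjusted p was 0.0727. Over the alternatives, 17 or 18 for each gene, Nuf2 and Exo1 kept their call, while Plk1 and Cdc20 lost theirs under 5, Ccne1 under 9, Odc1 under 6, Lss under 1, Idi1 and Cyc1 under 10 and Fdps under 7. With the mean of a gene's probe sets, Lss changed by 1.04 (adjusted p = 0.105) and Fdps by 0.64.

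Haematopoietic stem cell genes fell as a group, with a median of -1.03 over 38 measured genes, of which 10 fell, 2 rose and 26 did not pass (23 lower and 2 higher adjusted over the list alone; adjusted p = 1.81e-10; adjusted p = 0.131 with an estimated correlation). Sult1a1, Trpc6 and Kit were among those that fell, and Socs2 among those that rose. Of 17 megakaryocyte and platelet genes 5 fell, or 8 adjusted over the list alone, among them Pf4 by 3.09 (SE 0.41) and Treml1 by 2.11 (SE 0.31), with a median of -1.02 (adjusted p = 2.8e-05; adjusted p = 0.19 with an estimated correlation). Of 16 multipotent and lymphoid-primed progenitor genes, Ighm fell by 4.47 (SE 0.36), Lsp1 fell by 1.01 (SE 0.17) and Cd48 rose 1.07 (SE 0.13), with 9 lower and 1 higher adjusted over the list alone (median -1.13, adjusted p = 8.18e-05; adjusted p = 0.42 with an estimated correlation). Of the 11 probe sets of Ighm, 9 lay under background on each array and the other 2 changed by -4.28 and -4.47. With the mean of all 11 the change was -0.70 (adjusted p = 0.0552). Among other genes that antibody-secreting cells express, Igk was at 12.74, Jchain at 10.89 and Sdc1 at 10.42 in LSK cells. They were at 3.57, 5.12 and 7.21 in WT LICs (limma adjusted p = 0.000479, 0.000281 and 0.0507). Igk and Sdc1 were chosen after their values were seen. Whether the LSK sort held antibody-secreting cells was not tested, so the falls of Ighm and Jchain cannot be read as a change in progenitor cells. Among 19 genes of the Hoxa and Hoxb clusters with Meis1 and Pbx, 3 fell, Hoxa3, Hoxb4 and Hoxa10, by 1.91, 2.06 and 2.15, and 8 fell adjusted over the list alone (median -0.73, adjusted p = 0.000556; adjusted p = 0.131 with an estimated correlation). Genes of surface proteins reported on chronic myeloid leukaemia stem cells shifted downwards, with 4 of 24 called lower, Kit, Dpp4, Cd27 and Csf2ra, and 7 lower and 1 higher adjusted over the list alone (median -0.28, adjusted p = 0.0134; adjusted p = 0.377 with an estimated correlation), and without LSK replicate 3 the adjusted p was 0.059. Of these, Kit kept its call under each alternative, and Csf2ra, Dpp4 and Cd27 lost theirs under 15, 10 and 10 of 18 (adjusted p up to 0.151, 0.215 and 0.107). Hoxb4, Hoxa10 and Hoxa3 lost theirs under 11, 8 and 3, Lsp1 under 5 and Treml1 under 2.

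Of 22 monocyte and macrophage genes 3 fell, or 4 adjusted over the list alone, Lyz2 by 1.48, Lyz1 by 1.19 and F13a1 by 2.26 (median -0.60, adjusted p = 0.0172; adjusted p = 0.549 with an estimated correlation), and their adjusted p was 0.061 without LSK replicate 1 and 0.102 without WT LIC replicate 2. Granulocyte genes shifted upwards by a median of 0.39, with 1 of 24 called, Ms4a3, and 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.0389; adjusted p = 0.521 with an estimated correlation). Their call was lost after median centring or quantile normalization, among genes above the 40th percentile, and without LSK replicate 2 or 3 or WT LIC replicate 1 or 2 (adjusted p = 0.111, 0.059, 0.0547 and 0.0606 for these arrays). Interferon-stimulated genes had a median of -0.57, with none of 31 called and 2 lower adjusted over the list alone (adjusted p = 0.00379; adjusted p = 0.644 with an estimated correlation), and their adjusted p was 0.134 without LSK replicate 3 and 0.286 without WT LIC replicate 3. Of 19 imprinted genes, 3 fell, Sgce by 1.62, Grb10 by 1.21 and Peg12 at least 2.39-fold, with 3 lower and 1 higher adjusted over the list alone (adjusted p = 0.0195; adjusted p = 0.19 with an estimated correlation). Grb10 and Ms4a3 lost their call under 9 alternatives, F13a1 under 8, Lyz1 and Peg12 under 7 and Sgce under 1. With the mean of a gene's probe sets, Lyz1 changed by -0.73 and Grb10 by -0.66.

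Sex-linked transcripts separated LSK cells from the LICs. The Y-linked Eif2s3y was at 1.51 ± 0.20 (SD, n = 3) in LSK cells, 9.43 ± 0.25 (SD, n = 3) in WT LICs and 9.53 ± 0.39 (SD, n = 2) in Ezh2 KO LICs, and the Y-linked Kdm5d was at least 14.5-fold higher in WT LICs than in LSK cells (adjusted p = 0.0064). Xist, expressed from the inactive X chromosome of females, was at 12.55 ± 0.13 (SD, n = 3) in LSK cells, at 10.68 and 11.06 on WT LIC replicates 1 and 2, and at 4.35 on WT LIC replicate 3. On the Ezh2 KO arrays it was at 10.69 and 11.18. Xist was chosen after its values were seen. WT LIC replicates 1 and 2 and both Ezh2 KO arrays thus held Y-linked and Xist signal together. WT LIC replicate 3 held Y-linked signal with Xist near background. Without genes of the X and Y chromosomes, a setting chosen after the data were seen, 406 genes changed between WT LICs and LSK cells, 73 between Ezh2 KO and WT LICs and 421 between Ezh2 KO LICs and LSK cells. WT LIC replicate 3 also stood apart in other genes: Dntt, the terminal transferase of lymphoid progenitors, chosen after its values were seen, was at 12.14 there and at 9.89 and 9.58 on the other WT LIC arrays.

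The count of 424 moved when single arrays were left out: 207, 209 and 206 without LSK replicates 1, 2 and 3, 176 and 177 without WT LIC replicates 1 and 2, and 643 without WT LIC replicate 3. Centring each array on its median moved the median change of all genes from 0.02 to 0.15 and the share of calls that were higher from 37.0% to 58.3%, so the balance of rises and falls is relative to the scaling. All 14 lists that passed lost their call with an estimated correlation, while 10 of 34 passed with fry. Single arrays moved some list medians by over 1.5 times. Without LSK replicate 3 the imprinted, Hox and interferon medians were -0.18 (from -0.28), -0.40 and -0.30, and without WT LIC replicate 3 the granulocyte, surface protein and interferon medians were 0.25, -0.42 and -0.17. The oxidative phosphorylation median was 0.12 without WT LIC replicate 1, and the monocyte median -0.37 without WT LIC replicate 2. Of 45 called genes followed through the alternatives, 17 kept their call under each.

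The second comparison asked what loss of Ezh2 changed within LICs. Ezh2 KO LICs had higher levels of B cell genes, p53 target genes and immediate early genes. The p53 and B cell lists kept their call with an estimated correlation, and the immediate early list lost it (adjusted p = 0.163 with an estimated correlation). Of 12393 genes, 79 changed, 73 higher and 6 lower in the knockout. Igll1, a surrogate light chain of the pre-B cell receptor, rose 5.23 (SE 0.47, adjusted p = 0.00753), to 10.83 ± 0.74 (SD, n = 2) from 5.61 ± 0.45 (SD, n = 3). Of its 2 probe sets the dimmer moved by 1.82.

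The 5 other rises picked by the naming rule were those of Pou2af1, Cxcl2, Sdc4, Fosb and Rag1. Pou2af1, a B-cell transcriptional coactivator, was at least 42.6-fold higher in Ezh2 KO LICs (adjusted p = 0.00985), and Rag1, a recombinase of antigen receptor genes, at least 37.7-fold higher (adjusted p = 0.00985). The chemokine gene Cxcl2 was at least 16.8-fold higher (adjusted p = 0.0279) and the immediate early gene Fosb at least 19.3-fold higher (adjusted p = 0.0288). Sdc4, a cell-surface proteoglycan, rose 5.45 (SE 0.84, adjusted p = 0.0437), from 5.20 in WT LICs to 10.65, against 9.21 in LSK cells. Apart from Ezh2, the genes that fell were Ptpn22, a phosphatase of lymphocyte signalling, by 2.52 (SE 0.40, adjusted p = 0.0497), Zfp932 by 1.79 (SE 0.26, adjusted p = 0.0331), the non-coding RNA Neat1 by 1.72 (SE 0.25, adjusted p = 0.0304), Lss by 1.34 (SE 0.20, adjusted p = 0.0351) and Stat6 by 1.12 (SE 0.17, adjusted p = 0.0363). Without Ezh2 KO LIC replicate 2 none of these genes but Ezh2 and Igll1 kept its call, and over the alternatives the adjusted p reached 0.273 for Cxcl2, 0.2 for Sdc4, 0.227 for Fosb, 0.277 for Ptpn22 and 0.315 for Lss.

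p53 target genes rose as a group. Of 22 measured, 3 rose, none fell and 19 did not pass, or 13 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.72e-11; adjusted p = 0.0182 with an estimated correlation). Trp53inp1, which encodes a p53-induced stress protein, rose 1.71 (SE 0.21, adjusted p = 0.021), Zmat3 rose 2.98 (SE 0.38, adjusted p = 0.0217) and Phlda3, an inhibitor of AKT, rose 2.51 (SE 0.34, adjusted p = 0.0279). A second, dimmer probe set of Trp53inp1 moved by 0.17, and with the mean of both the change was 0.94 (adjusted p = 0.223). Without Ezh2 KO LIC replicate 1 the adjusted p was 0.0645, 0.0912 and 0.121 for Trp53inp1, Zmat3 and Phlda3, and without replicate 2 it was 0.128, 0.127 and 0.0909. Of 13 cyclin-dependent kinase inhibitors and related brakes, Cdkn2c rose 2.07 (SE 0.30, adjusted p = 0.0304), with 3 higher adjusted over the list alone (median 0.29, adjusted p = 0.000258; adjusted p = 0.143 with an estimated correlation). Cdkn2a, which encodes p16 and p19ARF and is a known Polycomb target, did not pass (adjusted p = 0.0707). It passed with a trended and robust prior (adjusted p = 0.0362), and the alternatives reached 0.224. It lay at 8.46 and 6.69 on the Ezh2 KO arrays, between 2.40 and 4.51 on the WT LIC arrays, and between 2.34 and 2.97 on the LSK arrays. Cdkn1a, which encodes p21, was at 10.17 against 8.81 (difference 1.36, SE 0.35, adjusted p = 0.205). Cdkn1c differed by 0.15 (adjusted p = 0.856). Cdkn2b was at 4.04 in WT LICs and under background, at 3.90, in Ezh2 KO LICs (adjusted p = 0.947), and both differences changed sign under other settings. Cdkn2c lost its call under 9 of 18 alternatives (adjusted p up to 0.145).

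B cell genes rose, with 5 of 15 called, none lower and 8 higher adjusted over the list alone (median 1.18, adjusted p = 1.09e-09; adjusted p = 0.0314 with an estimated correlation). Among genes above the 40th percentile, which leaves out dim members, the median was 3.85. Vpreb3 rose 4.29 (SE 0.35), Cd79a, a signalling chain of the B-cell receptor, rose 3.69 (SE 0.34) and Spib was at least 7.82-fold higher, each with an adjusted p of 0.00753. Pax5, a B-lineage transcription factor chosen after its values were seen, was under the background level in every group, at 2.53, 2.77 and 2.40 in LSK cells, WT LICs and Ezh2 KO LICs. Ebf1, another such factor chosen in the same way, was higher by 3.85 in Ezh2 KO LICs but did not pass (limma adjusted p = 0.361). Its 3 probe sets moved by 3.76 to 4.01. The tested one, the brightest, was spread over the WT LIC arrays, at 7.062, 2.698 and 5.735. The others lay at 3.68 or lower and 4.566 or lower in WT LICs. In Ezh2 KO LICs they lay at 6.492 or higher and 7.573 or higher. No p is given for them singly. Among 16 multipotent and lymphoid-primed progenitor genes, 2 rose, Rag1 and Blnk, and also 2 adjusted over the list alone (median 0.84, adjusted p = 2.1e-07; adjusted p = 0.244 with an estimated correlation). Blnk lost its call under 8 of 17 alternatives, Rag1 under 2 and Spib under 1.

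Of 23 immediate early and heat shock genes, Atf3 was at least 5.52-fold higher (adjusted p = 0.0178) and Fosb rose, with 11 higher adjusted over the list alone and a median of 1.41 (adjusted p = 5.35e-07; adjusted p = 0.163 with an estimated correlation). Among genes above the 40th percentile this median was 0.518, and with values under 32 raised to 32 it was 0.795. Of 7 measured fetal-type haematopoiesis genes reported as EZH2 or PRC2 targets, Igf2bp3, an oncofetal RNA-binding protein, rose 3.73 (SE 0.52, adjusted p = 0.0288), with 4 higher adjusted over the list alone (median 0.74, adjusted p = 0.00102; adjusted p = 0.105 with an estimated correlation). Of 19 imprinted genes, the growth regulator Grb10 rose 2.19 (SE 0.25, adjusted p = 0.0144), with 5 higher adjusted over the list alone (median 0.27, adjusted p = 0.00153; adjusted p = 0.105 with an estimated correlation). In the Hoxa and Hoxb list, Pbx3 rose 1.87 (SE 0.23, adjusted p = 0.0193), with 2 of 19 higher adjusted over the list alone (median 0.21, adjusted p = 0.00956; adjusted p = 0.161 with an estimated correlation). In the stem cell list, Bmi1, a Polycomb repressive complex 1 subunit, rose 1.30 (SE 0.16, adjusted p = 0.0193) and was alone of 38 both over all genes and adjusted over the list alone (median 0.15, adjusted p = 0.00531; adjusted p = 0.364 with an estimated correlation). Igf2bp3 and Pbx3 lost their call under 7 alternatives, Fosb and Grb10 under 6, Bmi1 under 5 and Atf3 under 4. With the mean of its probe sets, Grb10 changed by 1.01 (adjusted p = 0.0821). With values under 32 raised to 32, the medians of the fetal-type, imprinted and Hox lists were 0. The fetal-type median was 0.327 with the mean of a gene's probe sets and 1.24 among genes above the 40th percentile.

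Erythroid genes shifted downwards, with a median of -1.02 and all 24 below 0, but none passed singly or adjusted over the list alone (adjusted p = 4.85e-05; adjusted p = 0.501 with an estimated correlation). The erythroid median was -0.55 without WT LIC replicate 1 and -1.74 without WT LIC replicate 3, where Rhag passed singly (adjusted p = 0.00334). Granulocyte genes (median -0.46, adjusted p = 0.0137), MYC target genes (median -0.22, adjusted p = 0.0207) and oxidative phosphorylation genes (median -0.12, adjusted p = 0.0121) passed downwards with no member called in either way, and their adjusted p was 0.364, 0.501 and 0.655 with an estimated correlation. These lists lost their call without Ezh2 KO LIC replicate 2, as did the stem cell and Hox lists. The MYC target and oxidative phosphorylation lists also lost theirs without WT LIC replicate 1 (adjusted p = 0.183 and 0.319). STAT5 target genes (median 0.20, adjusted p = 0.00688) and endothelial and stromal genes (median 0.05, adjusted p = 0.0253) passed upwards with no member called in either way, and their adjusted p was 0.364 and 0.163 with an estimated correlation and 0.331 and 0.14 without Ezh2 KO LIC replicate 2. The median of the endothelial and stromal list was -0.0064 without WT LIC replicate 1, where the test still passed upwards. The list of 67 developmental transcription factor genes classically held by Polycomb had no member called, over all genes or adjusted over the list alone, with a median of -0.06 and a mean of 0.02, which differ in sign (adjusted p = 0.621, direction down).

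**Figure D2:**
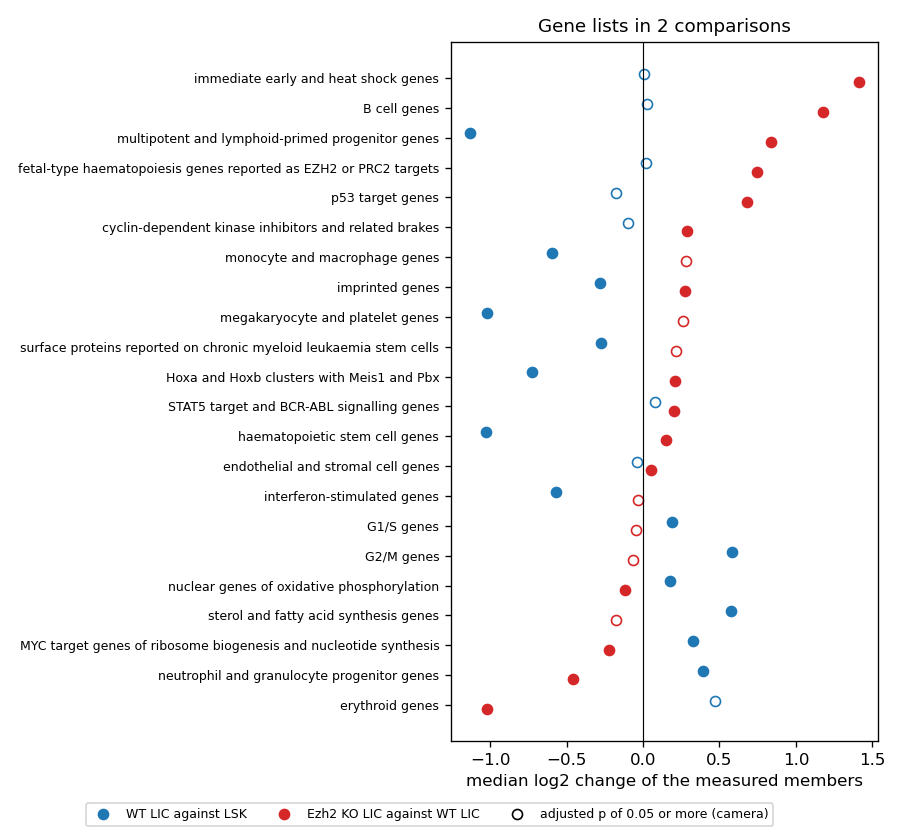
Median log2 change of the measured members (x axis) of each gene list that passed in at least 1 of the comparisons shown (y axis), for WT LICs against LSK cells and Ezh2 KO against WT LICs. Filled points had a camera adjusted p under 0.05 with the preset correlation and open points did not. Immediate early genes had a median of 1.41 and B cell genes of 1.18 in the Ezh2 comparison, while erythroid genes had -1.02.

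Of the 73 genes that rose without Ezh2, 41 lay at or under background in WT LICs and 27 in both WT LICs and LSK cells. Of all 12393 genes, 29.5% lay at or under background in WT LICs. The count of 79 was 25 and 37 without WT LIC replicates 1 and 2, 40 without Ezh2 KO LIC replicate 2, and 146 (95 higher, 51 lower) without WT LIC replicate 3. Single arrays also moved list medians by over 1.5 times. Without Ezh2 KO LIC replicate 2 the immediate early median was 0.70, the granulocyte -0.07, the STAT5 0.0040, the Hox 0.04, the oxidative phosphorylation -0.0085, the endothelial 0.0076, the kinase inhibitor 0.47 and the imprinted 0.49. Without Ezh2 KO LIC replicate 1 the granulocyte median was -0.81, the Hox 0.46, the stem cell 0.52, the STAT5 0.37, the endothelial 0.12 and the oxidative phosphorylation -0.25. Without WT LIC replicates 1, 2 and 3 the stem cell median was 0.28, 0.23 and 0.29 and the imprinted 0.18, 0.43 and 0.45. The STAT5 median was 0.10 without WT LIC replicate 1, the endothelial 0.15 without replicate 2, and the oxidative phosphorylation -0.07 and -0.20 without replicates 1 and 3. Of 25 called genes followed through the alternatives, Cd79a, Igll1 and Vpreb3 kept their call under each, as did the p53 and B cell lists.

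The third comparison placed Ezh2 KO LICs beside normal LSK cells. It called 430 genes, 200 higher and 230 lower in Ezh2 KO LICs. Igll1 rose 6.46 (SE 0.47, adjusted p = 0.00143), or 3.47 with the mean of its 2 probe sets, and Enah and Ccn3 were at least 89.4-fold (adjusted p = 0.000229) and 30.8-fold (adjusted p = 0.000229) higher. Pmaip1 was at least 81.2-fold higher (adjusted p = 0.00981) and Spats2 rose 5.50 (SE 0.90, adjusted p = 0.0252). Jchain fell by 6.66 (SE 0.36, adjusted p = 0.000287), and Cavin2, Sult1a1 and Rab6b, a vesicle-transport GTPase, were at least 28.7-fold, 20-fold and 15.7-fold lower (adjusted p = 0.00255, 0.00405 and 0.0099). Trpc6 fell by 3.87 (SE 0.51, adjusted p = 0.0133), Gt(ROSA)26Sor was at least 10.1-fold lower (adjusted p = 0.0116) and Ezh1 fell by 1.82 (SE 0.32, adjusted p = 0.0292). Without Ezh2 KO LIC replicate 1 the calls of Pmaip1, Spats2, Rab6b, Trpc6, Gt(ROSA)26Sor and Ezh1 were lost, and without replicate 2 those of Pmaip1, Spats2 and Ezh1. Without any 1 LSK array Spats2 was lost too, and Ezh1 without LSK replicate 3 or WT LIC replicate 1 or 2. Of 36 called genes followed, 16 kept their call under each alternative.

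Against LSK cells, 6 of 22 p53 target genes rose, or 7 higher and 1 lower adjusted over the list alone, among them Cdkn1a by 3.85 (SE 0.35, adjusted p = 0.00317) and Zmat3 by 3.88 (SE 0.38, adjusted p = 0.00453), with a list median of 0.53 (adjusted p = 0.000846; adjusted p = 0.157 with an estimated correlation). Of 15 B cell genes 6 rose, or 7 adjusted over the list alone (median 0.43, adjusted p = 2.67e-05; adjusted p = 0.157 with an estimated correlation). Among genes above the 40th percentile the B cell median was 3.76, and with values under 32 raised to 32 it was 0.285. Of 44 G2/M genes 5 rose, or 17 adjusted over the list alone, with Plk1 up by 1.46 (median 0.51, adjusted p = 9.05e-12; adjusted p = 0.188 with an estimated correlation). Of 38 stem cell genes 6 fell and 2 rose, or 14 and 3 adjusted over the list alone (median -0.79, adjusted p = 0.000184; adjusted p = 0.249 with an estimated correlation). Of 7 fetal-type genes 3 rose, Hmga2, Igf2bp3 and Arid3a, by 2.50, 4.54 and 1.09, or 4 adjusted over the list alone (median 0.75, adjusted p = 0.00562; adjusted p = 0.188 with an estimated correlation). Cdkn2a was at least 11.8-fold higher in Ezh2 KO LICs than in LSK cells (adjusted p = 0.0157), a call lost without LSK replicate 3 (adjusted p = 0.0502) or Ezh2 KO LIC replicate 1 (adjusted p = 0.0755) and with values under 32 raised to 32 (adjusted p = 0.0712). Of 23 immediate early and heat shock genes 3 rose, Atf3, Fosb and Egr2, or 5 adjusted over the list alone (median 0.62, adjusted p = 6.58e-05; adjusted p = 0.239 with an estimated correlation). Of 17 megakaryocyte and platelet genes 2 fell, Pf4 and Nrgn, or 7 adjusted over the list alone (median -1.03, adjusted p = 0.000355; adjusted p = 0.22 with an estimated correlation). STAT5 target and BCR-ABL signalling genes had 2 of 29 higher, Id1 by 3.94 and Socs2 by 3.41, or 4 higher and 3 lower adjusted over the list alone (median 0.39, adjusted p = 0.0067; adjusted p = 0.43 with an estimated correlation). Of 37 G1/S genes Exo1 alone rose, also adjusted over the list alone (median 0.23, adjusted p = 0.000846; adjusted p = 0.22 with an estimated correlation). Of 14 BCL2 family genes Pmaip1 alone rose, or 2 adjusted over the list alone (median 0.27, adjusted p = 0.0144; adjusted p = 0.239 with an estimated correlation). MYC target genes (median 0.27, adjusted p = 0.00404) and sterol genes (median 0.25, adjusted p = 0.0243) passed upwards, and interferon-stimulated genes (median -0.55, adjusted p = 0.00636) and erythroid genes (median -0.65, adjusted p = 0.0483) downwards, with 0 members called and 0 adjusted over the list alone. Their adjusted p was 0.43, 0.22, 0.711 and 0.815 with an estimated correlation. Among the genes named for these lists, Nrgn lost its call under 11 of the 17 or 18 alternatives (adjusted p up to 0.167), Egr2 and Arid3a under 8 (up to 0.172 and 0.158), Pf4 and Fosb under 5, Plk1 and Exo1 under 4, and Atf3 and Igf2bp3 under 1. Arid3a lost it without any 1 LSK or Ezh2 KO LIC array. The BCL2 family lost its call without Ezh2 KO LIC replicate 1, the STAT5, sterol and interferon lists without replicate 2, the interferon list also without LSK replicate 3, and the erythroid list without any array but LSK replicate 2 and WT LIC replicates 1 and 3.

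The count of 430 was 192, 225 and 172 without LSK replicates 1, 2 and 3, and 134 and 118 without Ezh2 KO LIC replicates 1 and 2. The share of higher calls was 46.5%, against 66.6% after median centring, which moved the median change of all genes from -0.02 to 0.12, and 57.3% after cyclic loess. List medians moved by over 1.5 times without Ezh2 KO LIC replicate 1 for interferon, immediate early and B cell genes (-0.86, 1.07 and 0.69), and without LSK replicate 3 for B cell genes (0.75). Without Ezh2 KO LIC replicate 2 they did for B cell, immediate early, STAT5, interferon, sterol and G1/S genes (0.67, 0.32, 0.18, -0.23, 0.12 and 0.15).

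The last comparison asked whether the difference between WT LICs and LSK cells was smaller in the knockout. Of the 424 genes called in the first comparison, 76.2% moved the opposite way between WT and Ezh2 KO LICs. Both comparisons share the 3 WT LIC arrays, and in 100 simulations with an unchanged knockout this share had a mean of 62.4% and a highest value of 65.8%. With values under 32 raised to 32, a floor chosen after the data were seen, the share was 69.8%, against a simulated mean of 61.2% and a highest of 65.1% under the same floor, over genes with a direction in both. The covariance of the log2 changes over all genes was -0.140, against a simulated mean of -0.050, and the correlation across genes, which are not independent replicates, was -0.35 against -0.19. These 100 simulations drew noise separately for each gene around the observed group means. They leave out variation that genes share on an array, so their range may be too narrow and sets no firm bound. The observed share itself ranged from 69.4% to 82.0% with single arrays left out. There were 23 genes both lower in WT LICs than in LSK cells and higher in Ezh2 KO than in WT LICs, against 1.57 for independent lists. At an unadjusted p under 0.05 in both comparisons there were 279, against 85.8 for independent lists and a mean of 66.4 in 20 simulations of unchanged groups, whose lists are shorter; part of the excess may come from the shared arrays. Of genes at an unadjusted p under 0.05 in the first comparison, 70.9% moved the opposite way in the second, against 83.9% in the same simulations, which hold no real difference between WT LICs and LSK cells. Ldhb, a lactate dehydrogenase subunit, was chosen after its values were seen: it was at 10.35 in LSK cells, 6.85 in WT LICs and 8.80 in Ezh2 KO LICs, and its 4 probe sets moved by 1.94 to 2.08 between the LIC groups. The call of this difference was lost without Ezh2 KO LIC replicate 2 (adjusted p = 0.0536). Against LSK cells 72 genes were higher and 109 lower in both LIC groups, against 2.53 and 4.96 for independent lists. At an unadjusted p under 0.05 in both there were 485 and 728, against 102 and 144 for independent lists and means of 69.5 and 67.0 in the simulations of unchanged groups, whose lists are shorter. Of genes at an unadjusted p under 0.05 in the first comparison, 91.1% had the same sign in Ezh2 KO LICs against LSK cells, and 84.4% did in the simulations of unchanged groups. With 3 LSK arrays the shared controls could not be split into parts of at least 2, so part of that overlap may come from them.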

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

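The signals below come from probe sets that entered no gene test because they carry no or several gene symbols; the way of counting them was chosen after the data were seen. In a limma fit over all probe sets, 25 of these 2246 were higher and 43 lower in WT LICs than in LSK cells (adjusted p under 0.05). In Ezh2 KO LICs 13 were higher and 0 lower than in WT LICs, and 35 were higher and 34 lower than in LSK cells. Of the 13 that rose without Ezh2, 4 carry several gene symbols. No biological explanation was tested for these probe sets.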

How the results depend on the processing

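The floor at an intensity of 32 was chosen after the data were seen. Of 106 called genes and 43 called lists followed through the alternatives, the test's direction changed for none, though the endothelial and stromal median turned to -0.0064 without WT LIC replicate 1, and 36 genes and 2 lists kept their call under each. Among uncalled genes, Cdkn1c turned to -0.028 after quantile normalization, and Cdkn2b to 0.20 without WT LIC replicate 2 and 0.48 without Ezh2 KO LIC replicate 2, from a lowest -0.76 without Ezh2 KO LIC replicate 1. Counts of changed genes are given for WT LICs against LSK cells, Ezh2 KO against WT LICs, and Ezh2 KO LICs against LSK cells in that order, from 424, 79 and 430. With arrays left out in turn they ranged from 176 to 643, 25 to 146 and 118 to 643. With array weights the first pair became 917 and 119. Raising values under 32 to 32 gave 244 and 40. The filter on dim genes left 32 for the Ezh2 comparison and a fit of its 5 arrays 35, with fewer genes or arrays by construction; that fit gave Ezh2 -2.10 with an adjusted p of 0.055, against 0.00231 to 0.0499 under the other alternatives. All probe sets gave 663 in the last comparison. The replicate block gave 252, 36 and 147; same-numbered arrays did not deviate together (correlations of -0.05 to 0.15), so the numbers are not taken to pair samples. It kept 109 of 149 followed genes and lists. With an estimated correlation 0, 2 and 0 lists passed in place of 14, 15 and 14. The share of opposite moves, 76.2%, ranged from 69.4% to 82.0% with arrays left out and was 69.83% with the floor at 32. Apart from the arrays left out and what construction explains, the cause was not tested. Of the medians of the called lists, 18 moved by over 1.5 times under that floor and 11 with the filter on dim genes. Under that floor Cdkn1c, Cdkn2b, Hba-a1 and Igf2 had no value in the Ezh2 comparison, nor Hba-a1 and Igf2 between Ezh2 KO LICs and LSK cells. Another background correction was not run, as it needs scanner values. Signal over background limits the folds of dim genes to lower bounds.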

Other observations

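The genes of this and the next paragraph were chosen after their values were seen, and no enrichment was tested. Among the 73 genes that rose in Ezh2 KO LICs, Enpep, which encodes an aminopeptidase found on early B cells, was at least 6.65-fold higher than in WT LICs (adjusted p = 0.000729), at 6.74 against 1.78 in WT LICs and 1.86 in LSK cells. The adhesion gene Mpzl2 was at least 9.23-fold higher (adjusted p = 0.00152), and Alpl, the tissue-nonspecific alkaline phosphatase, at least 4.84-fold higher (adjusted p = 0.000831). Enpep and Alpl kept their call under each alternative, and Mpzl2 lost it with values under an intensity of 32 raised to 32 (adjusted p = 0.0503). The Wnt receptor Fzd2 rose 3.11 (SE 0.31, adjusted p = 0.00985), Hoxc4 was at least 11-fold higher (adjusted p = 0.0163) and the BMP receptor Bmpr1a at least 10.6-fold higher (adjusted p = 0.0324). Of the desmosomal cadherins, Dsg2 rose 3.37 and Dsc2 was at least 2.75-fold higher (adjusted p = 0.0279 for each). With the mean of a gene's probe sets, Dsg2 changed by 2.24 and Fzd2 by 1.196. Fzd2 lost its call in a fit of the LIC arrays alone (adjusted p = 0.0549). Hoxc4, Bmpr1a, Dsc2 and Dsg2 each lost theirs without WT LIC replicate 1 or 2 or Ezh2 KO LIC replicate 1 (adjusted p up to 0.0861, 0.173, 0.762 and 0.166 over the alternatives).

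Igk, the immunoglobulin kappa light chain, lay at 12.74 ± 0.22 (SD, n = 3) in LSK cells against 3.57 ± 1.02 (SD, n = 3) in WT LICs and 3.78 ± 1.14 (SD, n = 2) in Ezh2 KO LICs (adjusted p = 0.000479 for WT LICs against LSK cells, limma). Ctr9 had 4 probe sets that disagreed: the brightest fell by 4.37 between LSK cells and WT LICs (adjusted p = 0.000149), and the others had changes of -0.57, -0.21 and -1.198.

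Of the tests that follow, those on B-lineage genes were chosen after the results were seen; all patterns were first noticed in the same data. In the p53 target list, 14 of 16 members outside the immediate early and stress response were higher in Ezh2 KO LICs. Their median was 0.56 and their camera p 0.00191 with an estimated correlation, so the rise was not confined to genes shared with that response. The list was taken up because it rose, so this p is not separate evidence of a rise. With the immediate early score of each array as a covariate, the p53 score differed by 0.901 between Ezh2 KO and WT LICs (95% interval 0.264 to 1.54, 4 residual degrees of freedom), against 0.796 without it. The slope of the covariate was -0.0758 (95% interval -0.473 to 0.322). The Ezh2 KO arrays had the highest immediate early scores, 8.47 and 9.13 against 7.03 to 7.92 on the others, so this adjustment reaches beyond the other arrays. With so uncertain a slope it cannot decide whether a stress response common to both scores raised them. Handling stress stays open, and a biological hypothesis is that loss of Ezh2 may raise p53 target genes in these cells.

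For the B-lineage genes, B progenitor cells carried through the knockout sort are a candidate explanation. Of 27 measured genes of a B progenitor list 55.6% were higher at an unadjusted limma p under 0.05, but 9 are in the B cell list and 6 in the lymphoid progenitor list that showed the rise; of the 12 others 3 were higher, 25%, short of the 75% set for that explanation and not under the 25% set against it. Among its genes that early B cells express strongly, chosen after their values were seen, Myb was at 13.01 in the knockout and 12.91 in WT LICs. Cd24a was at 12.30 and 12.63, and Dntt at 11.95 and 10.54. On WT LIC replicate 3 Dntt was at 12.14, above both Ezh2 KO arrays, at 11.98 and 11.92. In LSK cells Myb, Cd24a and Dntt were also high, at 13.07, 12.58 and 12.42, so they cannot report B progenitor cells. A small share of such cells and a change within the LICs cannot be told apart. A lower share of the main cell type would raise other mature types alike. The B cell score rose more than that of each of 8 such lists, by at least 1.82 (95% interval 1.23 to 2.40, monocyte genes). The lowest end of the 8 intervals was 0.783. For T and NK cell genes, 13 of 22 of them under background in WT LICs, the difference was 1.96 (1.29 to 2.64). The B cell list was taken up because it rose, so these differences cannot weigh for or against that explanation. The medians of the 8 other lists ran from -1.02 to 0.283, so those types did not rise alike. The gate on cells without lineage markers and the repeated sort are meant to remove mature B cells. LSK cells sorted on the same surface markers nevertheless held Igk, Jchain and Sdc1 at 12.74, 10.89 and 10.42. In Ezh2 KO LICs these genes were at 3.78, 4.23 and 9.39. The LIC gate also required GFP, so the LSK values do not show what it would pass. Whether cells were carried over stays open. An effect of Ezh2 loss within the cells was not tested.

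Calls between WT LICs and LSK cells were in excess on chromosome 6, with 43 against 24.8 expected (Fisher's exact test over 21 chromosomes, adjusted p = 0.00928), and 34 of them were lower in WT LICs. Immunoglobulin kappa genes do not account for this, since without them the unadjusted Fisher p was 0.000887, against 0.000442 with them. A segment of another genetic background might bunch the calls, but the densest run of 50 neighbouring genes held 6, against a median of 7 and a range from 6 to 9 between the 5th and 95th percentiles of 10000 shuffles. That meets the bound set against a segment, no more than the median, by less than the spread of the shuffles, so a difference spread along the chromosome stays open. No biological explanation was tested.

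Other splits of the 6 LSK and WT LIC arrays are too few to give a share under 0.05. The real split, the 1 of 10 with the most, gave 424 genes and 14 lists, and the highest of the others gave 0 genes and 9 lists.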
